A study of Xenopus laevis with 4 samples.

How the data were processed

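The samples were total RNA from pools of dorsal or ventral pancreatic buds of anaesthetised tadpoles, collected before fusion and frozen until enough had been gathered, per the labels. A pool yielded between 1 and 5 ng of RNA according to the sample descriptions, while the labelling protocol speaks of 10 µg as the typical input; how the amounts relate is not stated, so an amplification step is neither recorded nor excluded. Copy RNA was labelled with biotin by in vitro transcription from oligo(dT)-primed cDNA, and 15 µg of it was fragmented, per the labels' protocols. Such priming favours the 3′ ends of transcripts.

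The deposited values are linear-scale probe-set intensities, 1 column per array, and MAS5 is named in the submitters' processing notes without a version. The scaling target, the background settings and the detection calls are not stated, so whether a dim probe set was detected is unknown. The means of the deposited intensity over the probe sets that are not controls were 100 on each array, which shows that the arrays had been scaled to each other before deposit. Medians were 21.8, 24.2, 23.8 and 23.7 and highest values 6183, 5861, 7443 and 6937 in dorsal replicates 1 and 2 and ventral replicates 1 and 2. No probe set had an identical value in any pair of arrays. Scaling to a common mean hides any difference in total RNA per cell, and values of MAS5 are noisy where they are low.

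Of 15611 probe sets, 120 were controls and were left out of all tests. Among the remaining 15491, the platform annotation gave 9304 exactly 1 gene symbol, 195 several and 5992 none; a probe set with several symbols or none was tested but not named. Symbols were brought up to date through gene identifiers in a RefSeq table of the *Xenopus laevis* assembly v10.1, which matched 9227 of the 9304 and changed 2 symbols. The suffixes .L and .S mark the long and short homeologous chromosomes, and probes of one copy may also bind transcripts of the other. The annotation names no genome build for the array, so no positions are given.

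The 2% trimmed means of the arrays (63.0, 63.3, 61.3 and 61.1) lay within 10% of each other, so by the rule fixed before the data were examined the deposited scaling was kept. A pseudocount of 6, the 20th percentile of all values, was added before log2. Probe sets with a mean log2 over the 4 arrays above its 40th percentile were tested, 9294 in number. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on all 4 arrays with no covariate, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. A log2 difference is dorsal minus ventral, and the error given with it is the moderated standard error. Fold changes on this scale understate the change of genes with low intensity.

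For the gene lists, each gene was represented by the probe set with the highest mean log2, which gave 5201 genes. Lists were tested with camera in limma, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 17 lists, and again with an estimated correlation. The lists covered pancreatic endoderm transcription factors, endocrine pancreas, exocrine pancreas, liver, intestine and stomach, mesenchyme and smooth muscle, endothelium, blood, neural and neural crest, skeletal muscle and notochord, kidney, ribosomal proteins, cell cycle, stress response, hedgehog with retinoic acid and BMP signalling, Wnt with FGF and Notch signalling, and tetraspanins with cadherins and claudins. They were written as symbol patterns before the data were examined, and the pattern for drug-metabolising cytochromes of the liver list also took in some related cytochrome genes. The mesenchyme list also held the thromboxane synthase gene tbxas1.L, and the tetraspanin list the integrin gene itga2b.2.L. Members removed by the filter were not tested. The tested part ran from 5 of 27 neural genes on the array to 69 of 72 ribosomal protein genes. It was 8 of 19 for endocrine pancreas and 15 of 31 for skeletal muscle. A gene dim in 1 bud could pass the filter through high values in the other. Of 757 genes with more than 1 tested probe set, 13 had probe sets over 1 log2 unit apart.

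Named genes followed a rule fixed before the data were examined. They were the 12 probe sets with the largest log2 difference in each direction, among those with 1 symbol past the threshold and with the same direction in all 4 dorsal-ventral array pairs, 1 per gene. Where fewer passed, places were filled in order of log2 difference from those with an unadjusted p under 0.05, and these are said not to pass. In addition the rule took up to 4 members of each list with the largest absolute difference, and 15 core genes (ins, gcg, sst, pdx1, ptf1a, pdia2, cpa1, tspan8, hhex, prox1, neurod1, foxa2, alb, ttr and fabp2) whatever their value. Other genes named in the text were chosen after their values were seen.

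The procedure was tested on simulated data for 9294 probe sets in 2 dorsal and 2 ventral arrays: 65% of 100 probe sets changed 2-fold and 99% of 100 changed 4-fold were recovered, with 6 false calls, and 0 calls were made when nothing changed. Simulated values were independent between probe sets and had the fitted spread, equal in both groups. In the real arrays the spread between dorsal replicates was 1.68 times the ventral one, so these rates may be too favourable for them. The alternatives were quantile normalization, median centring, pseudocounts of 1 and of 4 times the value used, no filter and a filter at the 60th percentile, eBayes without a trend, the replicate number as a block, an adjusted p threshold of 0.10, all probe sets of a gene in the lists, and each replicate left out in turn. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.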

Results

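Transcript levels were measured in pancreatic buds dissected from *Xenopus laevis* tadpoles before the dorsal and ventral buds had fused. The pancreas of vertebrates forms from a dorsal and a ventral outgrowth of the gut tube, and the ventral outgrowth arises next to the liver and bile duct. Each of the 4 samples was a pool of between 1000 and 3000 buds, with 2 pools of dorsal buds and 2 pools of ventral buds, each hybridised to its own 1-colour Affymetrix array. After control probe sets were left out, the mean deposited intensity was 100 on every array, and the medians were 21.8 and 24.2 in the dorsal arrays and 23.8 and 23.7 in the ventral arrays. The number of arrays limits the precision of every comparison. Nothing in the labels says whether the pools of one kind came from separate batches of embryos, so p-values measure only the spread between these samples, which may be technical. Across the 9294 probe sets tested, the ventral arrays resembled each other (Pearson r = 0.981 across probe sets) more closely than the dorsal arrays did (r = 0.949). Dorsal replicate 1 correlated more highly with ventral replicates 1 and 2 (r = 0.962 and 0.954) than with dorsal replicate 2, which stood at 0.943 and 0.938 with the ventral arrays. The SD of the log2 difference between replicates was 0.48 for the dorsal pair and 0.29 for the ventral pair.

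The series asks which genes differ between the dorsal and the ventral bud. Insulin transcripts dominated the dorsal side. The insulin gene ins.S had an intensity of 2320.0 ± 495 in dorsal buds and 57.5 ± 22.2 in ventral buds (SD, n = 2 each), a log2 difference of 5.22 ± 0.27 (SE) with an adjusted p of 0.000742. Its homeologue ins.L, the copy on the other subgenome of this allotetraploid frog, stood at 1309 ± 105 against 29.5 ± 4.52, a log2 difference of 5.21 ± 0.18 with an adjusted p of 0.00014. The fitted difference was 37.4-fold for ins.S and 37.1-fold for ins.L.

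Of the other genes higher in dorsal buds, pcsk2.L and cpe.L encode enzymes of hormone processing. Intensity of pcsk2.L, a convertase that processes prohormones, was 118 ± 52.2 in dorsal and 4.05 ± 1.72 in ventral buds, a log2 difference of 3.58 (adjusted p = 0.00957). For cpe.L, the carboxypeptidase that trims hormone precursors after the convertases, the log2 difference was 1.76 (adjusted p = 0.0293), and its other tested probe set lay at 2.09 (adjusted p = 0.234). The protease inhibitor gene a2ml1.L, of the macroglobulin family, was higher in dorsal buds by 3.56 on the log2 scale (adjusted p = 0.0047), with intensities of 532 ± 117 and 40.2 ± 14.8. Another dorsal gene was darmin.L, which encodes a peptidase of the developing frog gut, at 965 ± 323 in dorsal and 87.0 ± 14.2 in ventral buds (log2 difference 3.35, adjusted p = 0.0047). The last of the dorsal genes past the threshold was the cornifelin gene cnfn.1.S (log2 difference 2.22, adjusted p = 0.0259). Ventral intensities of pcsk2.L and cnfn.1.S lay below the pseudocount of 6, which therefore sets the size of their differences: with 4 times the pseudocount these were 2.30 and 1.22. The next largest dorsal differences with an unadjusted p under 0.05 did not pass: c6.2.L at 1.73 (adjusted p = 0.392), the nuclease gene dnase1 at 1.63 (0.103), neurod1.L at 1.63 (0.195), and the secreted Wnt antagonist frzb, with frzb.L at 1.54 (0.258) and frzb.S at 1.51 (0.112). Without 1 array c6.2.L ran from 0.82 to 2.65, neurod1.L from 1.07 to 2.18 and frzb.L from 0.89 to 2.19.

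Among the ventral genes past the threshold were tm4sf4.L and tspan8.L, which encode membrane-spanning proteins, and itih2.S. Intensity of tm4sf4.L was 213 ± 57.6 in ventral and 3.70 ± 3.11 in dorsal buds (log2 dorsal minus ventral -4.51 ± 0.30, adjusted p = 0.00332). The tetraspanin gene tspan8.L, also called Tm4sf3, stood at 82.7 ± 11.5 in ventral and 1.72 ± 2.02 in dorsal buds (log2 difference -3.54 ± 0.27, adjusted p = 0.0047). The dorsal intensities of both genes lay below the pseudocount of 6, so the pseudocount sets the size of their differences, which were -3.08 and -2.05 with 4 times the pseudocount. The gene itih2.S, which encodes a plasma protein heavy chain made by liver, was at 959.6 ± 104 against 56.2 ± 12.2, a log2 difference of -3.97 ± 0.20 with an adjusted p of 0.000742 (-3.62 with 4 times the pseudocount). The clotting factor genes f12.L and f9.S differed by -2.30 (adjusted p = 0.0471) and -2.27 (adjusted p = 0.0133), and proc.S, the anticoagulant protein C, by -1.85 (adjusted p = 0.0333). Enzyme genes past the threshold were akr1d1.L, a bile acid synthesis reductase, at -2.62 (adjusted p = 0.0091), and agxt.L, a peroxisomal aminotransferase, at -1.23 (adjusted p = 0.0392). With 4 times the pseudocount f12.L was at -1.25, f9.S at -1.41, proc.S at -1.21 and akr1d1.L at -1.62. The remaining named ventral genes were MGC115605 (-2.08, adjusted p = 0.0259), the protease inhibitor serpinb6.L (-1.58, adjusted p = 0.033) and the prostaglandin D synthase hpgds.L (-1.55, adjusted p = 0.0401). The largest ventral difference that did not pass, in the set with an unadjusted p under 0.05, was the retinol carrier rbp4.L at -2.63 (adjusted p = 0.117), which ran from -3.53 to -1.74 without 1 array. In the same ventral arrays, the skeletal muscle list had a median of -1.18 and the blood list a median of -0.92, as given with the gene lists.

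**Figure D1:**
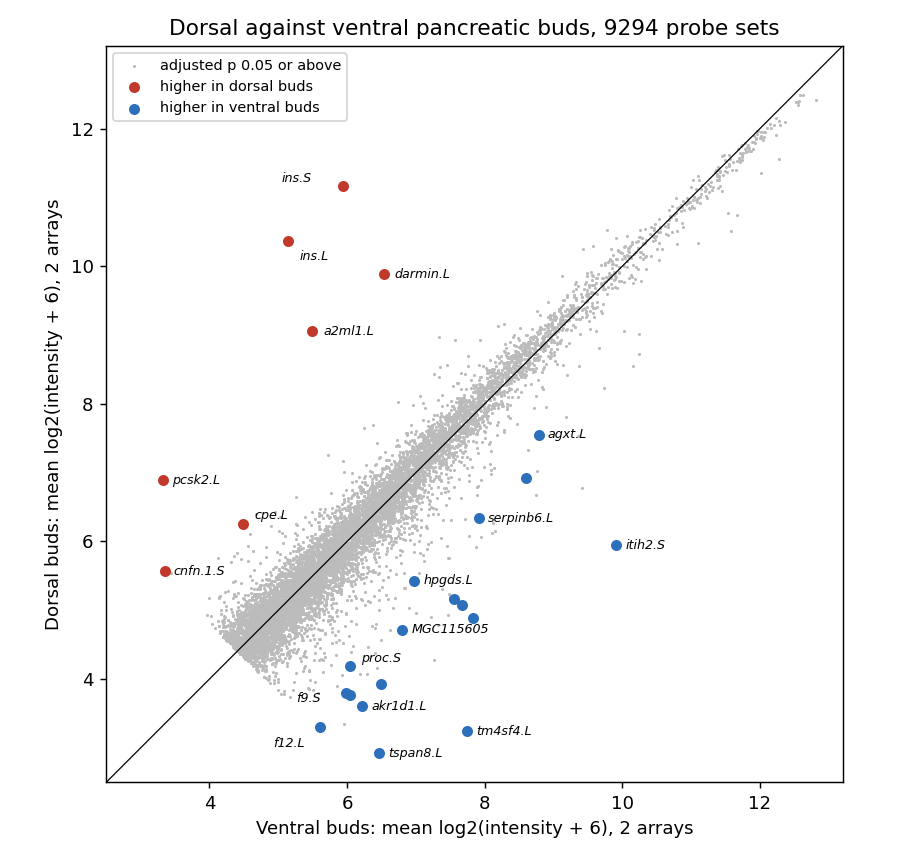
Mean log2(intensity + 6) of each of the 9294 tested probe sets in dorsal buds (vertical axis) against ventral buds (horizontal axis), 2 arrays each, with the line of equality; coloured points passed an adjusted p of 0.05 in limma and carry a name where the annotation gives 1 gene. The 7 red points, led by the insulin genes, lie above the line, and the 17 blue points, with tm4sf4.L, itih2.S and tspan8.L farthest out, lie under it.

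With limma and Benjamini-Hochberg adjustment over 9294 probe sets, 24 differed at an adjusted p under 0.05, 7 higher in dorsal and 17 higher in ventral buds. They named 18 genes, 7 dorsal and 11 ventral, and the 6 probe sets without a gene name were all higher in ventral buds, the farthest at -2.94. An unadjusted p under 0.05 was reached by 801 probe sets, 317 dorsal and 484 ventral, where 465 would be reached by chance. Fold changes and log2 differences are on the log2(value + 6) scale and understate the change of dim genes. In 10 of the 18 genes the dimmer group had a mean below 21.5, the highest value of the empty control probe sets, so the order of the genes by size depends on the pseudocount. Without dorsal replicate 1 the count was 902, without dorsal replicate 2 it was 348, and it was 4 without ventral replicate 1 and 4 without ventral replicate 2, in each case with a lone array taken to vary like the other group. Over these fits the log2 difference of ins.S ran from 4.86 to 5.59, of ins.L from 5.08 to 5.34 and of itih2.S from -4.17 to -3.77. All 18 named genes kept their direction. This had to follow, since each pointed the same way in all 4 dorsal-ventral array pairs.

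Differences larger than the spread between replicates were mostly in the ventral direction. A difference of at least 2-fold in the same direction in all 4 dorsal-ventral array pairs was seen for 82 probe sets, 11 higher in dorsal and 71 higher in ventral buds. The 2 other ways to split the 4 arrays gave 7 and 0 such probe sets. Without the size criterion, 39.9% of tested probe sets pointed the same way in all 4 pairs. Averaged over all ways to split the 4 arrays, the share is 33.3%. Probe sets are not independent and the shares of the other splits were not computed, so no excess over chance is shown. With a pseudocount 4 times as large the count of 82 was 43, and with the dim-probe filter at the 60th percentile it was 49.

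**Figure D2:**
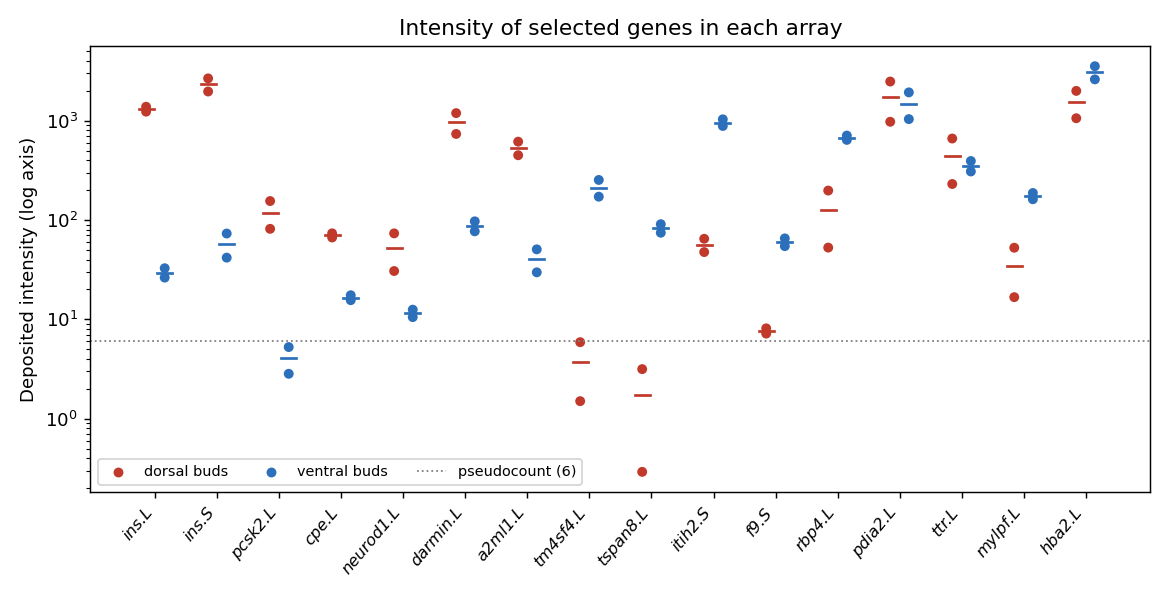
Deposited intensity (log axis) of 16 genes in each of the 4 arrays; each point is 1 array, the bar is the mean of the 2 arrays of a kind, and the dotted line is the pseudocount of 6. The insulin genes, pcsk2.L, cpe.L, darmin.L and a2ml1.L separate with dorsal above ventral, tm4sf4.L, tspan8.L, itih2.S and f9.S with ventral above dorsal, and the points of pdia2.L and ttr.L overlap.

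Endocrine pancreas genes were higher in dorsal buds as a group. Of 19 such genes on the array, 8 passed the filter and were tested. Of these, 4 passed over all probe sets tested, ins.L, ins.S, pcsk2.L and cpe.L, and 7 passed when adjusted over the list alone, all of them dorsal. The other 3 were the transcription factor genes neurod1.L (1.63) and insm1.L (1.42, adjusted p = 0.0808 over all probe sets) and the granule protein gene chga.L (0.97). Ventral means of these genes were 11.5, 14.6 and 9.56, below the highest empty control at 21.5, so the sizes of their differences depend on the pseudocount. The median log2 difference was 1.69 (camera adjusted p = 9.7e-14), and the adjusted p was 0.362 with an estimated correlation. The list kept its call without each replicate in turn, and its median was 1.03 with no filter. The other hormones could not be compared: gcg.L (glucagon) lay between 1.27 and 5.53 and sst.1.L (somatostatin) between 3.81 and 10.9 in the 4 arrays, too dim to be tested.

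Exocrine pancreas genes leaned to the dorsal side, less firmly. The 13 genes tested had a median of 0.53 (camera adjusted p = 0.0169, and adjusted p = 0.78 with an estimated correlation); 0 passed over all probe sets in limma, 3 had an unadjusted p under 0.05, and 2 passed when adjusted over the list alone, dnase1 (1.63) and the creatine synthesis gene gatm.L (0.82). The digestive enzyme genes were spread widely between replicates: amy2b.S was at 105 ± 135 in dorsal and 15.2 ± 2.57 in ventral buds, and cpb1.S at 129 ± 144 and 51.3 ± 42.5. Some lay near 0 or on the ventral side: ctrc.L at -0.26, ctrb1.L at -0.17, prss1.L at -0.07 and ctrl.L at 0.18. On the dorsal side, cel.1.L was at 0.53 and cel.2.S at 0.72. The carboxypeptidase gene cpa1.L differed by 0.89 (adjusted p = 0.52, and 0.37 to 1.41 on the log2 scale without 1 array), while the early pancreas marker pdia2.L, bright in both buds at 1729.7 ± 1065 and 1484 ± 630.4, differed by 0.14 (adjusted p = 0.955). Without dorsal replicate 1 the median of the list was -0.53 (adjusted p = 0.365), and without ventral replicate 2 it was 0.02 (adjusted p = 0.388). It was 1.06 without dorsal replicate 2 and 0.90 without ventral replicate 1. With the replicate number as a block the camera adjusted p was 0.00033, but the replicate numbers are not known to pair the pools. With no filter the median was 0.18 and the call was lost (adjusted p = 0.111), and with 4 times the pseudocount the median was 0.29.

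Transcription factors of pancreatic endoderm went both ways. Of 17 genes, 0 passed over all probe sets in limma and 7 had an unadjusted p under 0.05, and the list was not shifted (median 0.02, mean -0.14, camera adjusted p = 0.303). Adjusted over the list alone, 4 passed on the ventral side and 2 on the dorsal side. The ventral ones were gata5.S (-1.62), foxa1.S (-1.30) and hnf4a.S (-1.19), regulators of gut and liver endoderm, and tcf7l2.L (-0.66), a Wnt pathway factor. The brighter homeologue gata5.L was at -0.44 and did not pass. The dorsal ones were mnx1.S (0.94) and nr5a2.L (0.92). The dorsal mean of hnf4a.S (18.9) and the ventral mean of mnx1.S (16.4) lay below the highest empty control at 21.5. The sizes of their differences therefore depend on the pseudocount. The homeologue nr5a2.S was at -0.63, but its arrays overlapped, with 280 and 116 in dorsal and 337 and 237 in ventral buds. At 125 ± 27.8 and 85.1 ± 5.77, prox1.L differed by 0.50 (adjusted p = 0.584), with a range of 0.28 to 0.72 without 1 array. The ventral foregut gene hhex.L was too dim to be tested, at 3.53 and 5.72 in dorsal and 16.2 and 11.9 in ventral buds. No probe set was named for pdx1, ptf1a, foxa2 or alb alone.

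Liver genes were higher in ventral buds in part. Of 32 genes, 2 passed over all probe sets, itih2.S and f9.S, and when adjusted over the list alone 10 passed on the ventral and 1 on the dorsal side, the protease inhibitor a2m.S (1.35). Beside rbp4.L, large ventral differences that did not pass over all probe sets were those of tf.L and serpina1.L. The iron carrier tf.L was at -2.55 (adjusted p = 0.197, from -3.51 to -1.58 without 1 array) and the antiprotease serpina1.L at -2.32 (adjusted p = 0.112). Homeologues of these genes differed less: tf.S, dim in both buds, was at -0.11, serpina1.S at -1.51 and the brighter rbp4.S at -1.23. The thyroid hormone carrier ttr.L was at 447 ± 305 in dorsal and 351 ± 59.8 in ventral buds (log2 difference 0.17, adjusted p = 0.943). The median of the list was -0.25 (camera adjusted p = 1.9e-06, and adjusted p = 0.563 with an estimated correlation). Without dorsal replicate 1 the median was -0.07 (adjusted p = 0.111), and without dorsal replicate 2 it was -0.90. It was -0.39 with the filter at the 60th percentile.

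Markers of muscle and blood were also higher in ventral buds. The 15 genes of the skeletal muscle and notochord list had a median of -1.18 (camera adjusted p = 7.4e-07, and adjusted p = 0.362 with an estimated correlation); 0 passed over all probe sets in limma, 9 had an unadjusted p under 0.05, and 8 ventral and 1 dorsal passed when adjusted over the list alone, the dorsal one being the cartilage and notochord collagen gene col9a1.L (0.95). Its largest differences were those of mylpf.L at -2.30, myl1.S at -2.11, myl1.L at -2.04 and tnnc2.L at -1.67, while atp2a1.S was at 0.05. Dorsal means of myl1.S (15.7) and tnnc2.L (11.7) lay below the highest empty control at 21.5, so the sizes of their differences depend on the pseudocount. Without dorsal replicate 2, myl1.S was at -1.04, myl1.L at -1.28 and tnnc2.L at -0.69, and the other tested probe set of myl1.L lay at -1.08. Among 13 blood genes the median was -0.92 (camera adjusted p = 1.9e-08, and adjusted p = 0.388 with an estimated correlation); 0 passed over all probe sets in limma, 10 had an unadjusted p under 0.05, and 8 passed when adjusted over the list alone, all ventral. These were led by the myeloperoxidase gene mpo.L (-1.72) and the globin gene hbg2.L (-1.22), followed by slc4a1.L, the red cell anion exchanger (-1.07), and hba2.L (-1.06), which was at 1529 ± 663 in dorsal and 3075 ± 658 in ventral buds. Without 1 array hbg2.L ran from -1.71 to -0.74 and hba2.L from -1.51 to -0.60. Both lists kept their calls without each replicate in turn, with a blood median of -0.60 without dorsal replicate 2 and -0.59 without ventral replicate 2. With no filter the muscle median was -0.43.

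Several further lists passed the camera test by small shifts. The tetraspanin, cadherin and claudin list (46 genes, median -0.12, adjusted p = 0.0322, and adjusted p = 0.362 with an estimated correlation) held tm4sf4.L and tspan8.L, its 2 genes past the threshold over all probe sets, with cd37.S (-1.04) as the third when adjusted over the list alone. Without dorsal replicate 1 its adjusted p was 0.0869, without dorsal replicate 2 it was 0.104 (median -0.02), and without ventral replicate 2 it was 0.0587. The call was also lost with a pseudocount of 1 (adjusted p = 0.148), with no filter (0.176) and with the filter at the 60th percentile (0.195, median 0.002). The list of mesenchyme and smooth muscle (22 genes, median -0.22, adjusted p = 0.0184, and adjusted p = 0.78 with an estimated correlation) was led by col3a1.S (-1.23), col6a1.L (-1.02), acta2.L (-0.80) and fn1.S (-0.78, with another of its probe sets at -0.20). Without 1 array col3a1.S ran from -1.68 to -0.78 and fn1.S from -1.15 to -0.40. The median of this list was 0.21 without dorsal replicate 1 (adjusted p = 0.816), -0.73 without dorsal replicate 2, -0.42 without ventral replicate 1 and -0.39 with the filter at the 60th percentile, and its adjusted p was 0.242 without ventral replicate 2. Genes of hedgehog, retinoic acid and BMP signalling (20 genes, median -0.24, adjusted p = 0.00386, and adjusted p = 0.562 with an estimated correlation; without dorsal replicate 1, median -0.09 and adjusted p = 0.317) included crabp2.L (-0.79), id4.S (-0.79) and, on the dorsal side, the retinoic acid synthesis gene aldh1a2.L (0.63). Ribosomal protein genes (69 genes, median -0.10, adjusted p = 3.3e-05, and adjusted p = 0.362 with an estimated correlation) shifted together by a small amount that quantile normalization removed (median -0.002, adjusted p = 0.881; median -0.06 without dorsal replicate 1 and with median centring), with rpl17.S at -0.36 and rpl4.S at 0.29. Cell cycle genes were the remaining dorsal list (47 genes, median 0.17, adjusted p = 0.013, and adjusted p = 0.362 with an estimated correlation), with mcm7.S at 0.60, mcm4.S at 0.58 and kif2c.S at 0.56, while e2f1.L was at -0.52. The adjusted p of the cell cycle list was 0.201 without dorsal replicate 1 and 0.129 without ventral replicate 1. In limma, 0 members of the mesenchyme, hedgehog, ribosomal and cell cycle lists passed, over all probe sets or when adjusted over the list alone, while 5, 3, 4 and 4 of them had an unadjusted p under 0.05.

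With all 4 arrays no shift was called for 6 lists besides the transcription factors. Intestine and stomach (9 genes, median -0.38, mean 0.07, camera direction ventral, adjusted p = 0.411) held darmin.L, which passed over all probe sets and when adjusted over the list alone, while sult1c1.L was at -0.86 and fabp2.L at -0.38. Without dorsal replicate 2 this list was called in the ventral direction (median -0.65, adjusted p = 0.0422), and without dorsal replicate 1 its median was -0.03. Stress response (30 genes, median 0.02, camera direction ventral, adjusted p = 0.882) held the immediate early gene egr1.L, at 1.33 in the dorsal direction, which passed when adjusted over the list alone but not over all probe sets (adjusted p = 0.0817). For kidney (6 genes) the median was 0.02 and the mean -0.11 (adjusted p = 0.598), for endothelium (8 genes) the median was 0.15 (adjusted p = 0.826), for neural and neural crest genes (5 genes) the median was -0.01 and the mean 0.03 (adjusted p = 0.826), and for Wnt, FGF and Notch signalling (29 genes) the median was -0.01 (adjusted p = 0.537). The signalling list was called in the ventral direction without dorsal replicate 2 (median -0.23, adjusted p = 0.0091), and its median was 0.24 without dorsal replicate 1 (adjusted p = 0.219). In limma 0 genes of these last lists passed, over all probe sets or when adjusted over the list alone, and an unadjusted p under 0.05 was reached by 1 kidney gene and 2 signalling genes. Of the 17 lists, 10 passed the camera test with the preset correlation, 3 dorsal and 7 ventral. With an estimated correlation 0 passed, and the lowest adjusted p was 0.362. That setting has little power with 4 arrays, so the lost calls do not show that correlation between genes made the shifts. For the cell cycle list the estimate was 0.0094, under the preset 0.01, yet its unadjusted camera p rose from 0.00535 to 0.107. For the tetraspanin list the estimate was -0.02. The other called lists had estimates above the preset: 0.75 for exocrine, 0.55 for endocrine and mesenchyme, 0.49 for blood and 0.43 for liver. Hedgehog stood at 0.17, muscle at 0.14 and ribosomal genes at 0.027. Where the true correlation exceeds the preset, camera p-values with the preset are too small.

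**Figure D3:**
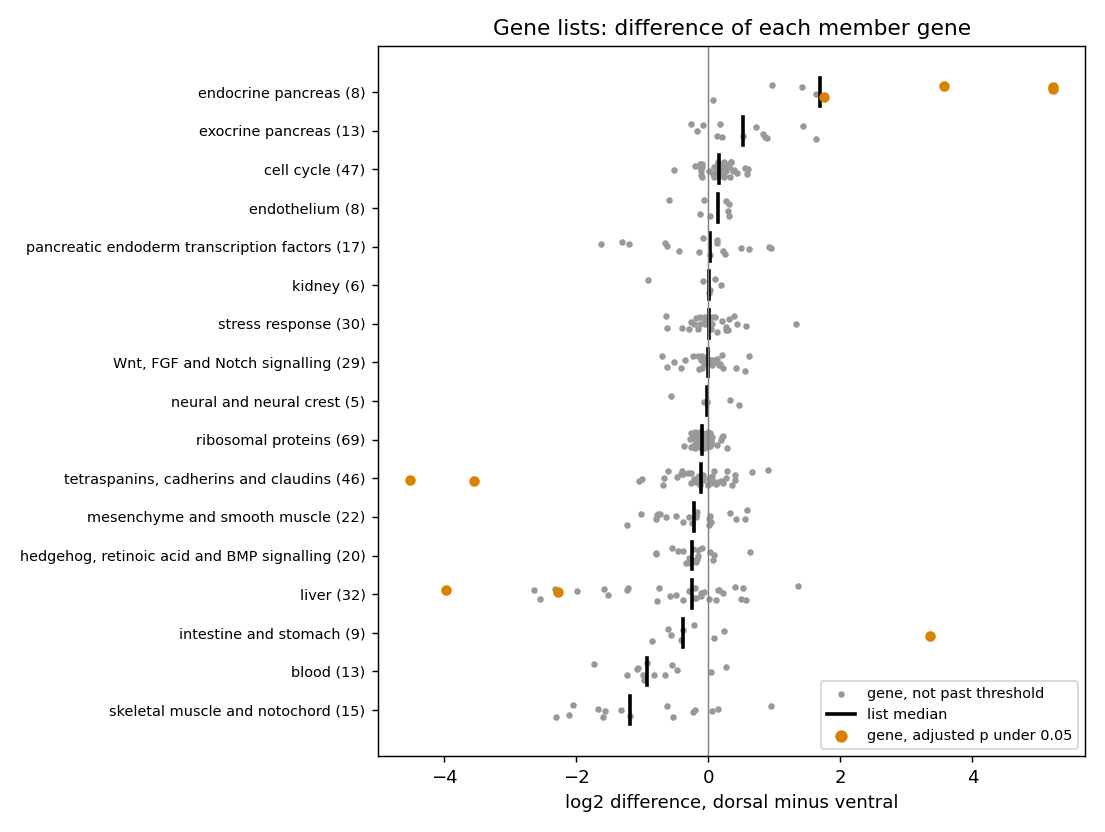
Log2 difference, dorsal minus ventral, of every tested gene of the 17 gene lists, with the number of genes in brackets; each point is a gene, orange where its adjusted p over all probe sets was under 0.05, and the black bar is the median of the list. Endocrine pancreas has the most positive median (1.69), skeletal muscle and notochord the most negative (-1.18), and most other medians lie close to 0.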

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

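Both tests of the muscle pattern were chosen only after the result was seen. The alpha-actin control probe sets, which were left out of every comparison, carried a signal that differed between the buds. The middle probe set of alpha-1 actin had a mean of 77.5 in dorsal and 263 in ventral buds, 3.39 times as high in ventral buds, and the highest empty control stood at 21.5. The dorsal means of the 5′ and middle probe sets of alpha-3 actin lay below that control, and no ratio is given for them. For the other alpha-actin probe sets the ratio of ventral to dorsal means ran from 2.93 to 3.85.

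These controls moved with the skeletal muscle list, whose median was -1.18. Scaling of the arrays was argued against, since under quantile normalization the median of the list was -1.17. Skeletal muscle dissected along with the ventral buds stays open as a candidate explanation, and so does expression within the ventral buds. That 6 of 6 alpha-actin probe sets, from alpha-1 and alpha-3 actin, were higher in both ventral arrays than in both dorsal arrays does not decide between them, since it is the signal already noticed and either explanation would give it. Probe sets of a muscle gene could disagree: the brightest one of atp2a1.S was at 0.05 and another at -2.53, and for ckm.L they were at -0.54 and -1.67.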

How the results depend on the processing

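The array weights and the shorter liver list were chosen only after the data were seen. All 18 named genes past the threshold kept their direction in every setting. Without 1 array this was fixed in advance, since each pointed the same way in all 4 array pairs. In every setting that left out no array and tested them, 11 passed, ins.L, ins.S and itih2.S among them. Over the 86 named genes and all alternatives, 1029 of 1169 values kept direction and side of the threshold, 39 lost the call, 84 gained it and 17 reversed. Without 1 array, the log2 difference moved by over 1.5 times for 39 of the 86 genes in at least 1 fit, and for 0 of the 18 past the threshold. Passing on the same arrays favours genes with close replicates, so this contrast is no separate evidence of stability. Of these 18, 7 moved by over 1.5 times with 4 times the pseudocount: pcsk2.L (2.30), cnfn.1.S (1.22), tspan8.L (-2.05), akr1d1.L (-1.62), f12.L (-1.25), f9.S (-1.41) and proc.S (-1.21). Among the 39 genes that moved without 1 array, those that kept their sign include acta2.L (-1.36 to -0.23), crabp2.L (-1.21 to -0.36) and col6a1.L (-1.56 to -0.48), none of them past the threshold. The count of 24 probe sets was 13 with the filter at the 60th percentile, where fewer were tested, 59 at an adjusted p under 0.10 and 57 with array weights. Without 1 array it ran from 4 (without ventral replicate 1 or 2, when the spread came from the dorsal pair alone) to 902 (without dorsal replicate 1, when it came from the ventral pair alone). The replicate numbers are not known to pair the pools, and deviations of like-numbered arrays correlated at 0.0468 across probe sets. That value does not exclude a shared replicate effect in some lists. Exocrine genes were lower in replicate 2 in both buds, 12 of 13 each, while blood genes moved in opposite directions (medians -0.45 and 0.43). With the replicate block 67 passed, 11 dorsal and 56 ventral, the 24 included, and the 10 lists kept their calls. The count of 82 was 43 with 4 times the pseudocount and 49 with the 60th percentile filter.

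With an estimated correlation 0 of 10 lists kept the call: adjusted p was 0.362 for endocrine, muscle, ribosomal, cell cycle and tetraspanin lists, 0.388 for blood, 0.562 for hedgehog, 0.563 for liver, and 0.78 for exocrine and mesenchyme. Quantile normalization ended the ribosomal call (0.881). The tetraspanin list lost its call with a pseudocount of 1 (0.148), no filter (0.176) and the 60th percentile filter (0.195), the exocrine list with no filter (0.111, median 0.18). The neural list turned its direction under quantile normalization (0.973) and with no filter (0.922), uncalled throughout.

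Without 1 array, 4 to 11 lists were called. Adjusted p ran from 9.5e-21 to 1.0e-09 for endocrine, 5.8e-14 to 3.4e-05 for blood, 4.4e-10 to 3.5e-06 for muscle, 3.7e-05 to 0.0281 for ribosomal, 3.3e-15 to 0.111 for liver, 0.0065 to 0.201 for cell cycle, 0.00019 to 0.317 for hedgehog and 0.021 to 0.104 for tetraspanin lists. For lists that turned direction it ran from 2.4e-09 to 0.388 (exocrine), 4.4e-07 to 0.816 (mesenchyme), 0.0091 to 0.661 (Wnt), 0.0422 to 0.917 (intestine), 0.0935 to 0.716 (neural), 0.219 to 0.61 (stress) and 0.305 to 0.816 (endothelium). Genes that changed sign, with 0 calls among them in the fit of all arrays, had log2 ranges of -0.42 to 3.29 (amy2b.S), -0.55 to 2.28 (cpb1.S), -0.53 to 0.81 (pdia2.L), -1.30 to 0.54 (fabp2.L), -0.58 to 0.92 (ttr.L), -0.62 to 0.48 (gap43.L), -0.31 to 1.24 (tubb2b.S), -0.36 to 1.01 (tubb3.L), -0.41 to 0.26 (slc22a15.2.S), -0.081 to 0.48 (sall1.L), -0.30 to 0.50 (atp1b3.S) and -0.21 to 0.82 (aplnr.L). Apart from the causes given, the cause was not tested. Between 19.7% and 22.7% of the values of an array lay under the pseudocount, and detection above background is unknown for them.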

Other observations

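The liver tests and the 3′ bias test were chosen only after the result was seen; the tests of dim probe sets and of the listed genes were written before. A few genes picked after their values were seen did not pass the threshold, and their values describe no group. The eosinophil peroxidase gene epx.L was at 33.7 ± 5.71 in dorsal and 168 ± 75.7 in ventral buds (SD, n = 2 each; log2 difference -2.07, limma adjusted p = 0.0808), and the proteinase gene prtn3.S at 27.0 ± 3.46 and 99.6 ± 38.0 (-1.64, adjusted p = 0.102). The fibrinogen genes were measured with fga.S at -1.99 (adjusted p = 0.169), fgb.L at -1.58 (adjusted p = 0.0996) and fgg.L at -0.37 (adjusted p = 0.814), and the tyrosine breakdown gene fah.L was at -1.22 (adjusted p = 0.107). On the dorsal side of the liver list stood the protease inhibitor a2m.S, at 503 ± 217 and 184 ± 7.13 (1.35, adjusted p = 0.163).

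Replicates of one kind differed in tissue markers. Of 13 exocrine genes, 12 were lower in replicate 2 than in replicate 1 in dorsal buds (median -1.04) and 12 in ventral buds (median -0.89). Of 22 mesenchyme and smooth muscle genes, 19 were higher in replicate 2 in dorsal buds (median 0.61) and 20 in ventral buds (median 0.32). Of 32 liver genes, 27 were higher in dorsal replicate 2 than in dorsal replicate 1 (median 0.91), whereas the median between the ventral replicates was -0.20. Blood genes differed by a median of -0.45 between the dorsal and 0.43 between the ventral replicates.

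The higher level of liver genes in ventral buds was weighed against scaling and carried-over liver. Scaling of the arrays was argued against: the whole list had a median of -0.25, and under quantile normalization it was -0.24 with a camera adjusted p of 2.1e-06. The call itself was lost with an estimated correlation (adjusted p = 0.563) and without dorsal replicate 1 (adjusted p = 0.111). Liver tissue dissected along with the ventral bud, which lies next to the liver, stays open as a candidate explanation. Of the 18 list members with a dorsal mean under 100, 10 (55.6%) were higher in both ventral arrays. This share lay between the bounds set for and against carried-over liver, but it cannot decide the question. Picking members by a low dorsal mean, after a filter on the mean of all arrays, favours genes that are high in ventral buds. Carried-over liver and expression by the bud could both give such a share, and no baseline was computed for it. Expression by the ventral bud itself is a hypothesis of equal standing that pooled tissue leaves untested.

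Dorsal replicates lay further apart than ventral replicates, with an SD of the log2 difference 1.68 times as large. Noise of dim probe sets was argued against, since among the 2324 brightest probe sets tested the ratio was 1.91. A difference limited to genes of the fixed lists was argued against too, the ratio being 1.66 without all list members. Unequal 3′ bias of the dorsal RNA may contribute: the Gapdh ratio of 3′ to 5′ signal was 9.69 and 5.53 in the dorsal arrays, a log2 difference of 0.81, against 0.007 between the ventral arrays, but probe positions were not at hand to decide it. No biological explanation was tested for this pattern.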
